A study of Mus musculus with 16 samples.

How the data were processed

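The series holds 16 samples of mouse small intestinal crypt RNA, in 4 groups of 4 by genotype (wild type, or Villin-Cre with loxP-flanked Ifnlr1) and treatment (NT or IFNL). Per the labels' protocols, 15 ng of RNA was reverse transcribed and barcoded libraries were made with the Ion AmpliSeq mouse transcriptome panel, in which each gene is read through a short amplicon rather than along its whole transcript. The aligner, the counting program and the genome build are not given in the sources used here.

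The authors deposited 4 tables with 1 row per amplicon target. By inspection of their values, 2 hold raw read counts and 2 hold depth-scaled read values (RPM) of the same libraries. Per the file headers, each table has a gene symbol column, a target identifier column and 8 library columns named by barcode. The 32 library columns were not used in any result, because no barcode name occurs in the sample labels and a match by column order, table name or values would be a guess. Only the gene symbol and target identifier columns were used. They identify rows, and carry no measurement.

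Comparisons with a quasi-likelihood test of the read counts at an adjusted p threshold of 0.05, tests of gene lists, and an exact permutation test of Ifnlr1 had been planned before the data were examined. None of these tests was run. The planned rule for naming genes was to take Ifnlr1 and Zbp1, the genes with the largest changes past the threshold, and the members of fixed lists with the smallest p. Its parts that rest on tests could not be applied. The genes named are Ifnlr1, Zbp1 and members of the 31 fixed lists, together with Il10rb, Ifnl2 and Ifnl3 and the genes Gm49368, SPATA24 and Gm45193 that share transcript windows with list members, all of which were added after the panel was seen.

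The analysis of the panel was chosen after it was found that the library columns could not be assigned. Identifiers were compared between the 4 tables with Python 3.11.15 and pandas 2.3.3. Of 23930 symbols, 21913 matched a RefSeq gene symbol (GRCm38.p6), 741 matched a synonym of a single gene, and 1276 matched neither. Each of the 426 list members was looked up by its symbol, then by the alternative name fixed with it, then by RefSeq synonyms. Synonyms that belong to several genes were not used. A member that matched several rows by synonym was counted as without a row. For members with a target, all different 100 nt windows of their protein-coding transcripts in GENCODE M21 were collected, and a window was called shared when it occurred without mismatch, on the same strand, in a transcript of any other gene. The window count was tested on simulated transcripts with a known overlap. No coordinates are given, because the tables name no genome build.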

Results

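Expression was measured by targeted amplicon sequencing of RNA from epithelial cells of mouse small intestinal crypts, the glandular pockets that hold the intestinal stem cells. The 16 samples fell into 4 groups of 4 by genotype and treatment. Wild-type mice were set against mice that carry loxP-flanked Ifnlr1 alleles and a Cre recombinase under the Villin promoter, which acts in gut epithelium. Ifnlr1 encodes the ligand-binding chain of the interferon lambda receptor. Samples of each genotype were labelled either NT or IFNL. The series description states that mice of both genotypes received 11 Gy of ionizing radiation with the upper body shielded. The title of the series names type III interferon, epithelial pyroptosis and repair after acute intestinal injury as its subject.

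No difference in expression between genotypes or treatments is reported, and no level of any gene is given for any group. The 4 tables named their library columns by sequencing barcode alone, with 8 such columns in each table and 16 different barcodes in all. Of these 16 barcode names, 0 occurred in the labels of the samples. A barcode could therefore be tied to a genotype or a treatment only by the order of the columns, by the name of the table or by the expression values themselves, and none of these was used. The 5 planned comparisons were genotype under IFNL, genotype under NT, their interaction, and IFNL against NT in each genotype. They were not made, and sequencing depth per sample is not given for the same reason.

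The sample titles placed all 8 NT samples on chip 1 and all 8 IFNL samples on chip 2. Treatment and chip therefore coincided, and IFNL against NT within a genotype could not be told apart from a difference between chips. The 4 wild-type and 4 Cre samples of each treatment shared a chip, so that the genotype comparison within each treatment did not have this limit. With 4 samples in each of 2 groups there are 70 assignments of samples to groups, and the smallest p that a two-sided exact permutation test of a single gene can give is 0.0286.

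The tables used here listed 1 amplicon target for each of 23930 gene symbols, with identical identifiers in all 4 tables. Among the symbols matched to a RefSeq symbol or synonym, 18814 were annotated as protein coding and 3482 as long noncoding RNA. The 1276 unmatched symbols have no annotation here. The interferon lambda axis was represented by targets for Ifnlr1, for Il10rb, the receptor's second chain, and for the ligands Ifnl2 and Ifnl3. The search for shared transcript windows covered only list members, and these genes are in none of the lists. Whether the targets of Ifnl2 and Ifnl3 can be told apart is therefore open. A single target stood for Ifnlr1. Its position relative to the loxP-flanked part of the gene is not given in the sources used here, so it is open whether this target would register the deletion.

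Of 426 genes in 31 lists fixed in advance, 389 were matched to a target in the tables used here and 37 were not. Matching was by symbol or by a RefSeq synonym of a single gene, so a row under a synonym of several genes was not counted. Here and below, a gene called lacking, or without a row, is one that was not matched. A missing row therefore does not show that the panel lacks the gene. In turn, a match rests on the name alone. It was not checked that the panel used a symbol for the same gene as the list did. The interferon-stimulated genes were represented by 33 of 36 members. They included Irf7, a transcription factor of the interferon response, Mx1 and Mx2, antiviral GTPases, and Usp18, a negative regulator of interferon signalling. Members without a row in the tables used here included Isg15, a ubiquitin-like modifier, and Ifit3. The guanylate-binding and immunity-related GTPases, which act against intracellular microbes, were represented by 8 of 15 members. Among these GTPases, Gbp6, Gbp8, Gbp10, Irgm2, Iigp1, Tgtp1 and Tgtp2 had no row. Antigen presentation through MHC class I had 12 of 13 members, lacking Psme2, and MHC class II had 7 of 7.

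Genes of lytic cell death and the inflammasome were represented by 24 of 25 members, with Fadd lacking. Targets were present for Zbp1, a nucleic acid sensor, for Casp8, Ripk3 and Mlkl of the necroptosis and apoptosis machinery, and for the gasdermins Gsdmc, Gsdmc2, Gsdmc3, Gsdmc4 and Gsdmd, which form pores in the cell membrane. Gasdermin E was listed under its older symbol Dfna5.

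The lists for tissue renewal were nearly complete. Crypt base stem cell markers had 17 of 17 members, among them Lgr5, Ascl2 and Olfm4. Targets of p53, the main transcription factor of the DNA damage response, had 19 of 19. Mitosis genes had 20 of 21, lacking Ccnb1, the DNA replication genes had 17 of 18, lacking Pcna, and the regeneration and fetal-like programme had 17 of 18, lacking Sprr1a.

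Coverage of differentiated epithelial types was uneven. Goblet cell markers had 10 of 10 members and tuft cell markers 11 of 11. Enterocyte markers had 19 of 20, without Apoa4, and enteroendocrine markers had 12 of 13, without Neurod1. Paneth cells, which secrete antimicrobial peptides at the crypt base, were represented by 6 of 13 members. All 7 of the Paneth genes without a row were alpha-defensins, and the 6 that remained were Lyz1, Ang4, Mmp7, Pla2g2a, Itln1 and Habp2. Markers of other cell types that a crypt preparation can contain were covered for T cells with 10 of 10 members, for fibroblasts with 10 of 10, for endothelium with 7 of 7 and for myeloid cells with 12 of 13. Erythrocyte markers had 2 of 6, because none of the 4 globin genes of the list had a row.

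Some of the covered genes have stretches of transcript that are identical in another annotated gene. Genes were told apart by symbol and not by position, so overlapping genes of a single locus and separate gene copies were counted alike. The highest shares of different 100 nt windows found unaltered in another gene were 66.8% for Itgam and 66.0% for Mzb1. The genes with the most matches were Gm49368 for Itgam and SPATA24 for Mzb1. Matches were counted over all transcripts of a gene, so a gene with more transcripts could hold more of them. For Herc6 the share was 20.9%, with the most matches in Gm45193. Among gene families, 28.6% of the windows of Gsdmc2 occurred in another gene, with the most matches in Gsdmc3. The value was 28.4% for Gsdmc3, 20.2% for Gsdmc4 and 7.0% for Gsdmc. For Oas1a it was 40.9% and for Oas1g 38.2%. The heat shock genes Hspa1a and Hspa1b shared 48.6% and 49.9% of their windows. Within each of these pairs, each gene had the most matches in the other. In all, 15 of the 389 genes shared more than 10% of their windows with another annotated gene, and for Zbp1 the value was 0.0%. This count depended on the window length, which was assumed, and was 32 with windows of 50 nt and 10 with windows of 150 nt. Amplicon sequences are not given in the sources used here, so whether a particular target lies in a shared stretch is open.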

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

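The alternatives below were chosen after seeing the data. Matching list members by their first symbol alone gave 388 genes with a target, against 389. The number of genes sharing more than 10% of their transcript windows with another gene was 15 with windows of 100 nt, 32 with windows of 50 nt and 10 with windows of 150 nt. With windows of 100 nt, 2 genes shared more than 50% (Itgam and Mzb1). Shorter windows match more easily by construction. The settings fixed before the data were examined (other normalizations, filters, tools, the RPM tables, other sets of samples, a covariate for cell mixture, other set tests, and leaving out each library) were not run, because they apply to comparisons that were not made. No paired analysis was made, because no library column was assigned to a sample. The sample titles also name no pairs of samples between groups, and the planned comparisons were unpaired.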
